A study of Oryza sativa with 12 samples.

How the data were processed

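RNA sequencing covered 12 libraries, 3 in each of 4 groups. They came from the aerial organs of 12-day-old rice seedlings of 2 near-isogenic lines, kept at 28 °C or at 42.5 °C for 20 h. The labels describe total RNA taken up with the RNeasy Plant Mini kit and libraries made with the Illumina TruSeq RNA kit. They do not say whether replicates are separate plants or whether strands were kept apart. The p-values below therefore measure only the spread between samples as deposited, and reads of overlapping genes on opposite strands cannot be told apart.

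One deposited table holds all values. Per the submitters' processing notes, reads were aligned with HISAT2 2.0.5 and counted per gene with featureCounts 1.5.0-p3, which gave the deposited raw read counts, one column per library. For each of 4 pairs of groups the authors deposited a log2 fold change of the first-named over the second-named group, with a p-value and an adjusted p-value. The notes name DESeq2 1.20.0 for this step. No genome build or annotation release is given in the sources used here, so coordinates are those of the deposited table. All 12 count columns were used. The 12 FPKM columns and the group means of the authors' tests were not used, and the test results served only for comparison.

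Columns of the heat-treated libraries carry numbers that cannot be tied to a replicate number in the sample titles. They are called heat libraries 1 to 3 of each line, in the order of their numbers. Gene descriptions are protein domains given in the deposited table. The available reference table did not pair the gene identifiers with symbols. Names of the G protein subunits, of WR1, WR2 and LSI1 therefore come from general knowledge matched by identifier, and each was kept only where the deposited domain description fitted. Transcripts that the submitters added to the annotation are called unannotated and are given by chromosome and start.

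Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 4 groups, libraries were scaled by TMM, and 1 model with a mean for each group was fitted to all 12 libraries. Each comparison was tested with the robust quasi-likelihood F test, two-sided, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of F. The comparisons numbered 5: heat against 28 °C in each line, the lines at 28 °C, the lines under heat, and the difference of the heat responses (the interaction). Expression levels are CPM with TMM scaling, as mean ± SD of 3 libraries. Where 1 group had no read, the fold change is a lower bound against a floor of 3 counts per library. Where a group had 1 to 3 reads in all, only levels are given. Such floors cover counting error only.

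Gene lists were defined by domain wording or by identifier, 40 in all, of which 37 had at least 5 tested genes. Of the 40, 4 hold markers of other tissues or compartments: root markers, seed reserve and starch breakdown, meristem and young tissue, and organelle-encoded genes. With 4 tested genes the root markers had no list test. Lists were tested with camera in limma 3.58.1, two-sided, with a preset correlation of 0.01 between genes, and adjusted over the 37 lists of a comparison. Alternatives were camera with an estimated correlation and fry. Fry asks whether a list's genes move one way on balance, without a comparison with other genes. The comparisons, the 40 lists, the choice of named genes and most alternatives were fixed before the data were examined. Accidental matches of the domain wording were taken out, and 9 lists were added, after the descriptions were read and before any test. The added lists were adjusted on their own.

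Named genes followed a fixed rule. For each comparison it took the 8 largest rises and the 8 largest falls among called genes with an average log2 CPM of at least 1, an informative description and no overlap between the replicates of both groups. The condition on overlap was dropped for the interaction. From each list described, it took the called members with the largest change in the main direction and the largest in the other direction. TT2, the other G protein subunits, WR1, WR2 and the CAMTA genes were reported whatever their values. Genes named outside this rule are marked as chosen after their values were seen.

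The replicate numbers were checked for pairing, since both lines carry numbers 1 to 3 at 28 °C. Deviations from the group means were correlated across genes with an average log2 CPM of at least 1. The same-numbered libraries of the lines gave r = 0.429, 0.114 and 0.406, and those with different numbers -0.434 to 0.074. Across all tested genes the same-numbered r was 0.289, 0.0756 and 0.275. The third principal component, 2.58% of the variance, separated the numbers at 28 °C. By the first gene set the numbers pair the 28 °C libraries, by all tested genes the second pair falls short of an r of 0.1, though it lies above those with different numbers (-0.297 to 0.0422). The pairing comes from the data and not from the labels. A fit with the replicate number as a block at 28 °C was therefore an alternative, and its value stands beside each result whose call it changed.

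Other alternatives were RLE and total-count scaling, no filter and a stricter filter (CPM of at least 1 in at least 3 libraries), DESeq2 1.42.0, limma-voom, a fit on the compared groups alone, a threshold of 2-fold, omission of each library in turn, omission of genes within 5 Mb of TT2, and a gene length trend as offset. Alternatives planned for data deposited only as normalized values were not needed. The pipeline was tested on simulated data with 3 libraries per group. At a 2-fold change edgeR recovered 61.2% of the changed genes for the lines at 28 °C, 71.6% for the lines under heat and 46.3% for the interaction. At a 4-fold change it recovered 87.9%, 84.8% and 75.8%.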

Results

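Gene expression was measured by RNA sequencing in the aerial organs of 12-day-old rice seedlings of 2 near-isogenic lines, which share most of their genome but carry different alleles of TT2. NIL-TT2HJX (HJX below) is labelled wild type and NIL-TT2HPS32 (HPS32 below) is labelled loss of function. TT2, also known as GS3, encodes a gamma subunit of the heterotrimeric G protein, a membrane-bound signalling complex. Each line was kept at 28 °C or at 42.5 °C for 20 h, with 3 libraries per group. At 28 °C the HJX libraries held 16308041, 17871972 and 15559263 reads assigned to genes, and the HPS32 libraries 15904505, 16249300 and 16594903. Under heat the HJX libraries held 15859583, 15195234 and 17805120 assigned reads, and the HPS32 libraries 15269874, 14785975 and 15400813. Of the 40674 genes listed, 25473 passed the filter on low counts, and they held at least 99.9% of the reads of every library.

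The first principal component, 80.8% of the variance, separated heat from 28 °C, and the second, 7.36%, separated the lines under heat. TMM factors averaged 0.863 for HJX and 0.860 for HPS32 at 28 °C, 1.06 for HJX under heat and 1.27 for HPS32 under heat. Scaling by total counts alone moved the median log2 fold change of all tested genes to 0.32 for heat in HJX, 0.54 for heat in HPS32, 0.28 for the lines under heat and 0.28 for the interaction. With TMM these medians lay between -0.03 and 0.03. The changes below are relative to the TMM reference, and gene groups whose median turned under total counts are named as such. Unannotated transcripts took 0.644% ± 0.0484 of the reads in HJX and 0.640% ± 0.00817 in HPS32 at 28 °C. Under heat they took 2.31% ± 0.0440 and 2.06% ± 0.0211 (SD, n = 3). The share of mitochondrially encoded reads was 0.000353% ± 2.79e-05 in HJX and 0.000209% ± 1.46e-05 in HPS32 at 28 °C, and 0.0038% ± 0.00128 and 0.00501% ± 0.000806 under heat. Ribosomal RNA took 0.165% ± 0.0180 of the reads in HJX and 0.0965% ± 0.0321 in HPS32 at 28 °C, and 0.0930% ± 0.0127 and 0.120% ± 0.0234 under heat. Plastid-encoded reads were 0.00389% ± 0.000714 and 0.00331% ± 0.000337 at 28 °C, and 0.00192% ± 0.000119 and 0.00189% ± 0.000189 under heat.

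TT2 itself (Os03g0407400, chromosome 3, 16729501 to 16735109) was barely read in these organs. The 3 libraries of a group held 9 reads in all for HJX and 7 for HPS32 at 28 °C, and 8 for HJX and 16 for HPS32 under heat. This depth is below the filter, so no difference of TT2 between the groups was detectable, and the read counts do not check the genotype labels.

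The first comparison asked what 20 h of heat changed in HJX. Light harvesting and photosystem genes fell (60 of 68), while 17 of 29 small heat shock proteins and 72 of 132 other chaperones, which keep damaged proteins from clumping, rose and 9 and 31 fell. With an estimated correlation between genes the list test passed for the first of these groups (adjusted p = 0.0498) and not for the others (0.0734 and 0.236). The highest rise was that of the starch-degrading alpha-amylase Os08g0473900, from 0.777 ± 0.468 to 1420 ± 156 CPM (log2 10.84 ± 0.21 SE, adjusted p = 8.93e-17, n = 3 per group). The light-harvesting chlorophyll-binding gene Os01g0600900 dropped from 15300 ± 1740 to 138 ± 43.3 CPM (log2 -6.79 ± 0.27, adjusted p = 1.48e-10). In all, 19079 of the 25473 tested genes changed, 9698 upward and 9381 downward (12238 and 7289 under total counts), and 10796 of them by at least 2-fold.

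Further rises were those of Os03g0245800, a small heat shock protein of the Hsp20 family (0.228 ± 0.203 to 187 ± 22.8 CPM, log2 9.60 ± 0.24), and the neprosin-domain gene Os07g0179700 (log2 9.53 ± 0.33). The C1-domain gene Os08g0404900 went from 0.0243 ± 0.042 to 52.8 ± 1.99 CPM. Genes unread in HJX at 28 °C included Os03g0687400, a ribosome-inactivating protein, at least 34.2-fold higher under heat, and the patatin-like phospholipase Os08g0477100, at least 29.2-fold higher. The heat stress transcription factor Os06g0565200 was at least 28.2-fold higher. The unannotated zinc-knuckle transcript (chromosome 10, from 17702307) was at least 35-fold higher, with an adjusted p of 0.0117 that ranged from 3.83e-09 to 0.0812 over its alternatives. Its call was lost in the fit on both HJX groups alone. Among the falls, Os12g0169600, a fructose-bisphosphate aldolase of sugar metabolism, dropped from 355 ± 24.7 to 0.414 ± 0.15 CPM (log2 -9.75 ± 0.19, adjusted p = 1.99e-17). The xylanase inhibitor Os12g0583300 went from 94.2 ± 11.1 to 0.0399 ± 0.069 CPM, and the cellulose synthase Os04g0429600 from 23 ± 6.86 to 0.0208 ± 0.036 CPM. Genes left without a read under heat were the cytochrome P450 genes Os08g0262500, at least 80.5-fold lower, and Os03g0371350, at least 38.1-fold lower. The same held for the trehalose-phosphatase Os12g0505800, at least 47.8-fold lower, the terpene synthase Os08g0139700, at least 40.3-fold lower, and the ferric reductase Os04g0578600, at least 34.5-fold lower.

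Among the falling groups, 60 of 68 photosynthesis genes fell, 3 rose and 5 did not pass the test (median log2 -3.49, camera adjusted p = 1.84e-44, 0.0498 with an estimated correlation). They included Os01g0720500, another chlorophyll-binding gene (-7.37 ± 0.28), and the photosystem II gene Os08g0119800 (-5.99 ± 0.28). Of 46 lipid transfer proteins, which carry lipids to the cell surface, 33 fell and 5 rose (median -1.48, adjusted p = 5.05e-06, 0.0498 with an estimated correlation), and Os12g0115500 fell by 3.67 ± 0.24. No other list of the 37 passed in HJX with both correlations. In the chlorophyll synthesis group 6 of 9 genes fell and 2 rose (median -1.57, adjusted p = 0.000397, 0.0714 with an estimated correlation). Uroporphyrinogen decarboxylase, Os03g0337600, was at -3.09 ± 0.08 and the magnesium chelatase subunit Os03g0563300 at -3.08 ± 0.10. Phenylpropanoid and lignin genes had 28 of 38 members down and 6 up (median -2.40, adjusted p = 1.23e-05, 0.142 with an estimated correlation). The dirigent-like gene Os07g0637700 was at least 22.6-fold lower and the chalcone or stilbene synthase Os04g0116800 was at -6.23 ± 0.26. Ribosomal proteins had 135 of 235 members down and 55 up (median -0.42, adjusted p = 0.000286, 0.45 with an estimated correlation). The S30EA-type gene Os03g0856500 was at -4.12 ± 0.11 and ribosomal protein L6, Os03g0356300, at -3.23 ± 0.11. Of 31 aquaporins, which are membrane water channels, 19 fell and 6 rose (median -1.22, adjusted p = 0.00392, 0.148 with an estimated correlation). Here Os09g0541000 was at -6.33 ± 0.23, and Os10g0492600, unread at 28 °C, was at least 29.5-fold higher.

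Cuticular wax genes had 12 of 16 members down and 2 up (median -0.91, adjusted p = 0.0331, 0.45 with an estimated correlation, blocked adjusted p = 0.0626). Their members Os02g0814200 and Os09g0426800, of the WAX2 family, fell by 3.24 ± 0.28 and 2.73 ± 0.19. Cell wall genes had 71 of 120 members down and 26 up (median -0.89, adjusted p = 0.00392, 0.236 with an estimated correlation). Among them the pectinesterase Os07g0691100 went from 4.76 ± 0.889 to 0.0624 ± 0.108 CPM. Cytochrome P450 genes had 107 of 193 members down and 38 up (median -0.88, adjusted p = 0.00807, 0.28 with an estimated correlation). Genes that scavenge reactive oxygen had 50 of 103 members down and 31 up (median -0.30, 0.00 under total counts, adjusted p = 0.0458, 0.395 with an estimated correlation, blocked adjusted p = 0.0516). Glutathione S-transferases had 33 of 57 members down and 18 up (median -0.56, adjusted p = 0.05 as rounded from just under the threshold, adjusted p = 0.395 with an estimated correlation, blocked adjusted p = 0.0626).

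Of the rising groups, 17 of 29 small heat shock proteins rose and 9 fell (median 1.79, adjusted p = 0.000286, 0.0734 with an estimated correlation). Os11g0244200 was at least 15.1-fold higher, while Os07g0517100 fell by 1.31 ± 0.07. Of 132 other chaperones, 72 rose and 31 fell (median 0.40, adjusted p = 0.00669, 0.236 with an estimated correlation). The Hsp90 gene Os04g0108101 was at 6.15 ± 0.23 and the DnaJ gene Os01g0730500 at -4.04 ± 0.15. Splicing factors had 13 of 15 members up and 0 down (median 0.75, adjusted p = 0.00153, 0.0734 with an estimated correlation). SF3B1, Os02g0478900, was at least 22-fold higher and the PRP1-type factor Os01g0263600 was at 2.87 ± 0.10. Proteasome subunits, which degrade tagged proteins, had 27 of 38 members up and 1 down (median 0.36, adjusted p = 0.0034, 0.437 with an estimated correlation), with Os08g0529100 at 2.65 ± 0.14. Autophagy genes, which serve the recycling of cell contents, had 16 of 25 members up and 3 down (median 0.48, adjusted p = 0.05 as rounded from just under the threshold, adjusted p = 0.395 with an estimated correlation, blocked adjusted p = 0.0626), with the Apg6 gene Os03g0644000 at 1.89 ± 0.09. Adjusted over the list alone, the counts of these groups were the same except for phenylpropanoid genes (7 up), ribosomal proteins (136 down), glutathione S-transferases (19 up) and autophagy genes (4 down). Among marker lists of other tissues, seed reserve and starch breakdown genes had 9 of 14 members up and 2 down (median 1.00, adjusted p = 0.0113, 0.236 with an estimated correlation), with the same counts adjusted over the list alone. A second alpha-amylase, Os09g0457400, was at least 20.6-fold higher, with an adjusted p of 1.57e-05 that ranged from 4.97e-07 to 0.0712 over its alternatives. Its call was lost with DESeq2.

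Several groups did not pass the test in HJX. Heat stress transcription factors had 9 of 23 members up and 11 down (median -0.39, mean 0.24, test direction up, adjusted p = 0.496), and their member Os03g0161900 fell by 1.78 ± 0.33. Organelle-encoded genes had 9 of 16 members up and 5 down, and meristem genes 4 of 6 members down, each with an adjusted p of 0.424. Of the 4 tested root markers 3 fell, among them LSI1, Os02g0745100, a silicon channel of roots (-1.78 ± 0.26). The counts of these groups were the same adjusted over the list alone. Among G protein subunits, RGA1 (alpha, Os05g0333200) fell by 0.65 ± 0.08, and the gamma subunits RGG2 (Os02g0137800), DEP1 (Os09g0441900) and GGC2 (Os08g0456600) fell by 0.77 ± 0.09, 1.11 ± 0.25 and 1.33 ± 0.45. RGB1 (beta, Os03g0669200) rose by 0.20 ± 0.08, and RGG1 (Os03g0635100) was at 0.19 ± 0.24 (adjusted p = 0.479). WR1 (Os02g0202000) and WR2 (Os06g0604000), regulators of wax synthesis, fell by 0.66 ± 0.24 and 0.52 ± 0.11. CAMTA genes encode calmodulin-binding transcription factors. Of the 5, Os10g0375600 and Os03g0191000 rose by 0.71 ± 0.07 and 0.34 ± 0.07, Os04g0388500 and Os01g0923600 fell by 0.30 ± 0.07 and 1.01 ± 0.08, and Os07g0490200 was at 0.12 ± 0.07 (adjusted p = 0.107). Omission of a single library ended the call of RGB1 (without HJX replicate 1 or 3 or HJX heat library 1 or 3, adjusted p = 0.0816 to 0.117), WR1 (without HJX replicate 2 or 3 or HJX heat library 1, 0.0508 to 0.103) and GGC2 (without HJX heat library 2, 0.0519). Total-count scaling ended those of WR1 (0.191), WR2 (0.0906) and Os04g0388500 (0.976), within ranges over all alternatives of 0.0135 to 0.191, 5.36e-05 to 0.0906 and 9.21e-07 to 0.976, and the length offset those of WR1 (0.136) and Os03g0191000 (0.0881, range 1.48e-07 to 0.0881). Os07g0490200 passed under total counts (0.42, adjusted p = 2.08e-05, range 2.08e-05 to 0.341).

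The second comparison asked the same of HPS32. Here 59 of 68 photosynthesis genes fell, and 15 of 29 small heat shock proteins, 10 of 15 splicing factors and 20 of 38 proteasome subunits rose. With an estimated correlation between genes none of these groups, and 0 of the 37 lists, passed (adjusted p = 0.0839, 0.158, 0.18 and 0.604). The Hsp20 gene Os03g0245800 rose from 0.312 ± 0.116 to 310 ± 19.5 CPM (log2 9.93 ± 0.23, adjusted p = 5.97e-14), and the alpha-amylase Os08g0473900 from 0.5 ± 0.137 to 212 ± 18.5 CPM (log2 8.70 ± 0.21, adjusted p = 2.81e-15). Os01g0600900 fell from 14900 ± 756 to 406 ± 97.8 CPM (log2 -5.19 ± 0.25, adjusted p = 1.41e-09). In all, 17925 genes changed, 8653 upward and 9272 downward (14369 and 5063 under total counts), and 9246 of them by at least 2-fold.

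Genes unread in HPS32 at 28 °C were the C1-domain gene Os08g0404900, at least 40.8-fold higher under heat, the epimerase-type gene Os01g0633500, at least 27.7-fold higher, the NF-Y-type transcription factor Os10g0191900, at least 22.9-fold higher, and an unannotated retrotransposon-like transcript (chromosome 4, from 11348420), at least 13.4-fold higher. A pair of other such transcripts (chromosome 7, from 13867220, and chromosome 6, from 9893367) rose by 8.39 ± 0.33 and 8.11 ± 0.28. The methyltransferase gene Os03g0843800 fell by 9.91 ± 0.20, and the xyloglucan endotransglycosylase Os06g0335900, which loosens cell walls, was at least 48-fold lower. The dirigent-like gene Os07g0637700 was at least 32.1-fold lower, and the cellulose synthase Os04g0429600 fell by 8.14 ± 0.58. Levels near the floor under heat were those of Os12g0583300 (91.7 ± 13.6 to 0.0172 ± 0.0298 CPM), Os04g0578600 (10.9 ± 6.48 to 0.0172 ± 0.0298), the cysteine-rich secretory gene Os07g0129300 (9.74 ± 2.46 to 0.0178 ± 0.0308) and the unannotated trehalose-phosphate synthase-like transcript on chromosome 1, from 23669351 (8.52 ± 5.32 to 0.0171 ± 0.0296).

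Of 68 photosynthesis genes 59 fell and 4 rose (median -2.95, adjusted p = 7.98e-39, 0.0839 with an estimated correlation), with Os01g0720500 at -6.11 ± 0.26 and the photosystem II gene Os05g0508900 at -4.72 ± 0.11. Chlorophyll synthesis genes had 7 of 9 members down and 2 up (median -1.48, adjusted p = 0.000441, 0.0839 with an estimated correlation), with Os03g0337600 at -2.82 ± 0.08. Phenylpropanoid genes had 26 of 38 members down and 5 up (median -1.37, adjusted p = 0.000269, 0.18 with an estimated correlation). Lipid transfer proteins had 32 of 46 members down and 8 up (median -1.03, adjusted p = 0.0008, 0.0979 with an estimated correlation), with Os12g0114900 at -2.86 ± 0.13. Aquaporins had 17 of 31 members down and 5 up (median -1.16, adjusted p = 0.00159, 0.158 with an estimated correlation), with Os09g0541000 at -4.32 ± 0.19. Sugar transport, trehalose and raffinose genes had 30 of 49 members down and 10 up (median -0.62, adjusted p = 0.0342, 0.18 with an estimated correlation). The trehalose-phosphatase Os05g0128900 was at -6.87 ± 0.85 and the raffinose synthase Os06g0172800 at 2.08 ± 0.13. Reactive oxygen genes had 56 of 103 members down and 23 up (median -0.40, turned to 0.16 under total counts, adjusted p = 0.0124, 0.271 with an estimated correlation). Calcium sensors had 42 of 86 members down and 12 up (median -0.51, turned to 0.05 under total counts, adjusted p = 0.0342, 0.518 with an estimated correlation).

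Small heat shock proteins had 15 of 29 members up and 8 down (median 1.49, adjusted p = 0.000363, 0.158 with an estimated correlation), with Os01g0136100 at 6.20 ± 0.20 and Os03g0157600 at -1.15 ± 0.14. Proteasome subunits had 20 of 38 members up and 1 down (median 0.19, adjusted p = 0.0124, 0.604 with an estimated correlation), with Os08g0529100 at 2.94 ± 0.14. Splicing factors had 10 of 15 members up and 2 down (median 0.50, adjusted p = 0.0236, 0.18 with an estimated correlation), with Os01g0263600 at 2.60 ± 0.10. Seed reserve and starch breakdown genes had 6 of 14 members up and 3 down (median 0.42, adjusted p = 0.0358, 0.271 with an estimated correlation). The other chaperones had 62 of 132 members up and 40 down without passing the list test (adjusted p = 0.256), with Os04g0108101 at 4.82 ± 0.22 and Os01g0730500 at -4.59 ± 0.15. Heat stress transcription factors had 5 of 23 members up and 13 down (median -0.38, turned to 0.18 under total counts, adjusted p = 0.953), with Os06g0565200 at least 8.7-fold higher and Os03g0161900 at -2.78 ± 0.35. Ribosomal proteins had 84 of 235 members up and 81 down (median 0.03, mean -0.02, adjusted p = 0.911), with Os06g0546400 at 1.92 ± 0.11 and Os03g0856500 at -3.10 ± 0.11. Autophagy genes had 9 of 25 members up and 7 down (median -0.16, test direction up, median turned to 0.40 under total counts, adjusted p = 0.983), with Os03g0644000 at 1.13 ± 0.09 and the ATG101 gene Os12g0446700 at -1.30 ± 0.11. The wax gene Os02g0814200 went from 122 ± 17.3 to 30.4 ± 8.01 CPM, and the root marker LSI1 fell by 1.30 ± 0.25. Organelle-encoded genes had 9 of 16 members up and 3 down (adjusted p = 0.304), meristem genes 1 of 6 up and 3 down (adjusted p = 0.713), and root markers 2 of 4 down. Adjusted over the list alone, the counts of the groups given for HPS32 were the same except for photosynthesis (60 down), phenylpropanoid (27 down), sugar (31 down), proteasome (19 up), heat stress transcription factor (6 up) and autophagy genes (8 up).

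Among G protein subunits in HPS32, RGA1 fell by 0.38 ± 0.08, RGG2 by 1.09 ± 0.09 and DEP1 by 1.41 ± 0.25, while RGB1 (-0.02, adjusted p = 0.804), RGG1 (0.44, 0.0881) and GGC2 (-0.04, 0.943) did not pass. WR1 (-0.36, adjusted p = 0.192) and WR2 (-0.15, 0.242) did not pass. Of the CAMTA genes Os04g0388500 and Os01g0923600 fell by 0.50 ± 0.07 and 0.73 ± 0.08. The CAMTA genes Os10g0375600 (-0.04, adjusted p = 0.633), Os03g0191000 (-0.06, 0.465) and Os07g0490200 (-0.14, 0.081) did not pass. Total-count scaling turned the sign of RGA1 (0.19, adjusted p = 0.0513, range 0.000276 to 0.0513) and of Os04g0388500 (0.06, adjusted p = 0.468, range 2.24e-09 to 0.468), and ended the call of Os01g0923600 (0.0862, range 4.58e-13 to 0.0862). It also turned genes that did not pass upward past the threshold: RGB1 (0.54, adjusted p = 4.87e-06, range 4.87e-06 to 0.91), WR2 (0.41, 0.00385, range 0.00385 to 0.736), Os10g0375600 (0.52, 2.16e-06, range 2.16e-06 to 0.976), Os03g0191000 (0.50, 4.06e-06, range 4.06e-06 to 0.977) and Os07g0490200 (0.42, 2.05e-05, range 2.05e-05 to 0.336). The last 3 passed downward with the length offset (0.0128, 0.00276 and 0.000831), and Os07g0490200 also without HPS32 replicate 1 (0.0116). RGG1 passed with total counts (0.000568), the length offset (0.021) and the fit on both HPS32 groups alone (0.0481), within a range of 0.000568 to 0.26.

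**Figure D1:**
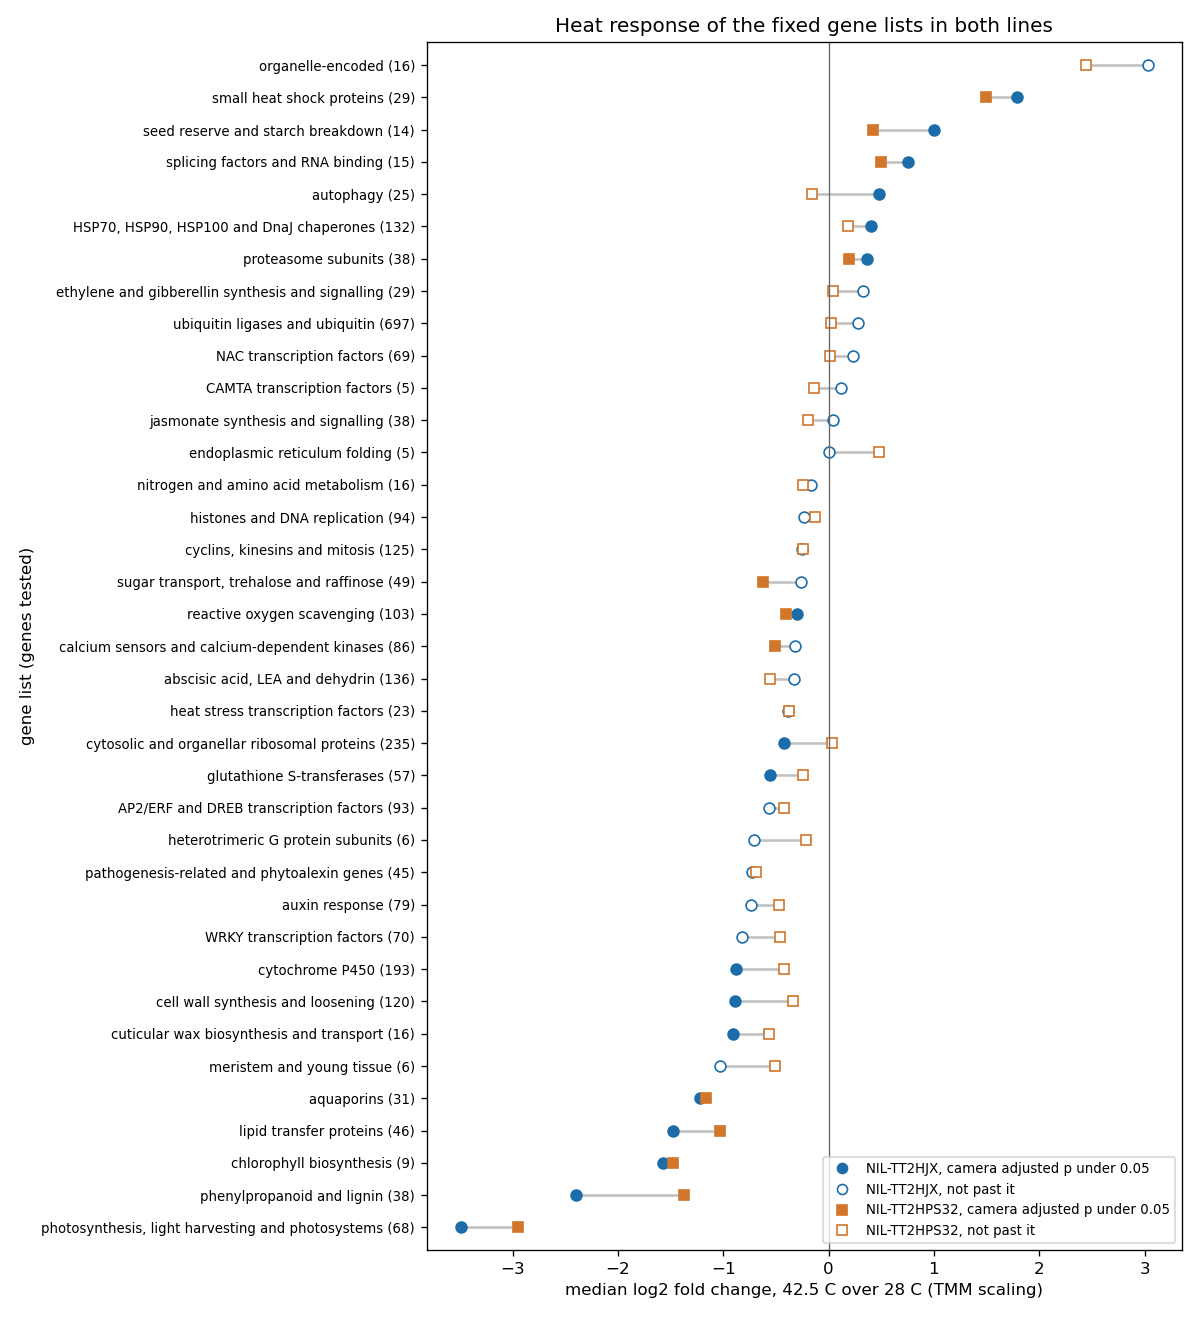
Median log2 fold change under heat of the 37 tested gene lists in HJX (blue circles) and HPS32 (orange squares), with filled symbols where camera gave an adjusted p under 0.05; 17 lists in HJX and 12 in HPS32 are filled. Photosynthesis lies lowest at -3.49 and -2.95 in HJX and HPS32, and total-count scaling turned the sign of 4 medians in HJX and 17 in HPS32.

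The heat responses of the lines share no library. Of the 15371 genes called in both, 14850 moved the same way and 521 moved oppositely. Across the 21633 genes called in either line the slope of the HPS32 response on the HJX response was 0.857 and Pearson's r was 0.899. Both describe genes, which are not independent replicates, so no p is given.

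The third comparison asked how the lines differed before heat. At 28 °C 22 genes differed, 11 higher and 11 lower in HPS32. The immune receptor-like NB-ARC gene Os03g0689400 (chromosome 3, 27517768 to 27521337) was at 1.74 ± 1 CPM in HJX and 12.2 ± 0.673 CPM in HPS32 (log2 2.83 ± 0.26, adjusted p = 4.28e-05). The dioxygenase Os03g0690500 (chromosome 3, 27580909 to 27582211) was at 26.2 ± 2.71 CPM in HJX and 6.18 ± 0.535 CPM in HPS32 (log2 -2.09 ± 0.13, adjusted p = 5.48e-08). The same directions held for both genes under heat.

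Higher in HPS32 were also the lysine decarboxylase-like gene Os09g0547500 (1.03 ± 0.14, adjusted p = 0.0038), the SNF2-type chromatin remodelling gene Os03g0101700 (0.90 ± 0.09, adjusted p = 2.17e-05), the transposase-like gene Os09g0268600 (0.80 ± 0.13, adjusted p = 0.017) and the BRCT-domain gene Os11g0191300 (0.42 ± 0.08, adjusted p = 0.0329). Lower in HPS32 were an unannotated retrotransposon-like transcript on chromosome 3, from 14019375 (-1.28 ± 0.19, adjusted p = 0.0329), an unannotated MADS-box transcript on chromosome 4, from 19042625 (-0.74 ± 0.12, adjusted p = 0.0206), the methyltransferase Os03g0843800 (-0.54 ± 0.10, adjusted p = 0.0329) and the SWIRM-associated gene Os03g0722100 (-0.44 ± 0.08, adjusted p = 0.0293). The KNOX homeobox gene Os03g0727000, of a family that keeps meristem cells undifferentiated, was at 1.66 ± 0.368 CPM in HJX and 0.0244 ± 0.0423 CPM in HPS32 (adjusted p = 0.01). The largest difference, chosen after the values were seen, was that of the undescribed gene Os12g0210601, at 0.241 ± 0.417 CPM in HJX and 18.4 ± 2.51 CPM in HPS32 (log2 6.25 ± 0.57, adjusted p = 0.0013). None of the G protein subunits, WR1, WR2 or the CAMTA genes passed (adjusted p = 0.802 to 0.995).

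None of the 37 lists passed at 28 °C with camera, 0 passed with the estimated correlation and 0 with fry, while 1665 single genes had an unadjusted p under 0.05. With the replicate block 66 genes were called, all 22 among them, and 3 lists, all lower in HPS32: auxin response (adjusted p = 0.0124), WRKY (0.0124) and AP2/ERF transcription factors (0.019). Omission of 1 library gave 3 lists without HJX replicate 1, 5 without HJX replicate 3, 7 without HPS32 replicate 1 and 1 without HPS32 replicate 2. Of the added lists, that of KNOX genes passed downward (median -0.10, mean -1.23, adjusted p = 7.33e-06, 0.00885 with an estimated correlation) with 1 of 6 genes called, also when adjusted over the list alone: Os03g0727000, whose own call ended in 3 omissions. The list of terpene synthases passed with the preset correlation but not with the estimated one (median -0.48, adjusted p = 3.5e-05 and 0.0878), with 0 of 21 genes called and 1 adjusted over the list alone. DESeq2 called 49 genes, limma-voom 13 and the fit on the 6 libraries at 28 °C alone 12. Omission of 1 library moved the count to between 8 (without HPS32 replicate 2; 13 without HPS32 replicate 3) and 26. Of the genes named by rule only Os03g0689400, Os09g0547500, Os03g0101700 and Os03g0690500 stayed called in every omission. The first had an adjusted p of 0.0777 in the 6-library fit (range over its alternatives 4.57e-28 to 0.0777). That fit also ended the calls of Os09g0268600 (0.0617, range 0.000308 to 0.153), Os11g0191300 (0.226, range 0.00153 to 0.226), Os03g0843800 (0.307, range 0.000444 to 0.307), Os03g0722100 (0.0834, range 0.00093 to 0.129) and the unannotated retrotransposon-like and MADS-box transcripts (0.659, range 3.94e-07 to 0.659, and 0.133, range 0.000507 to 0.133). Of the calls named by rule limma-voom ended 4 (0.0547 to 0.0788), total counts 2 (0.0592 each), no filter 1 (0.0563) and the block on the 6 libraries 1 (0.0509). Calls ended without HJX replicate 1 or 2 or HPS32 replicate 2 or 3 for Os09g0268600 (0.0527 to 0.153), and without HJX replicate 2 or any HPS32 replicate for the unannotated retrotransposon-like transcript (0.051 to 0.203). They ended without HJX replicate 3 or HPS32 replicate 1 or 2 for the unannotated MADS-box transcript (0.105 to 0.118), and without any library but HJX replicate 2 for Os03g0843800 (0.0935 to 0.235). They ended without any library but HJX replicate 1 for Os03g0722100 (0.0908 to 0.129), any but HPS32 replicate 1 for Os11g0191300 (0.0778 to 0.169), and without HJX replicate 2 or HPS32 replicate 2 or 3 for Os03g0727000 (0.061 to 0.117).

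Near-isogenic lines can keep donor DNA around a selected locus, so positions of the called genes were compared. Within 5 Mb of TT2 lay 1 of the 22 genes called at 28 °C, or 4.55%, against 2.32% of the tested genes (Fisher's exact test, two-sided, p = 0.404). With the replicate block the share was 7.58% (Fisher's exact test, p = 0.0186). On the whole of chromosome 3 lay 7 of the 22, or 31.8%, against 13.1% of tested genes (Fisher's exact test, p = 0.0189), 4 of them between 27 and 30 Mb. Under heat 2.49% of the called genes lay within 5 Mb of TT2 and 13.9% on chromosome 3 (Fisher's exact test, p = 0.122 and p = 0.00174).

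The fourth comparison asked how the lines differed under heat. More photosynthesis and ribosomal protein genes were higher in HPS32 than lower, and more chaperones, autophagy genes and genes of sugar transport, trehalose and raffinose were lower than higher. With an estimated correlation the sugar list passed (adjusted p = 0.0434) and the other lists named did not (0.0992 to 0.117). Total counts moved the median of all genes from 0.03 to 0.28, against a TMM chaperone median of -0.31. The DnaJ co-chaperone Os02g0693200 was at 299 ± 8.82 CPM in HJX and 66.3 ± 5.23 CPM in HPS32 (log2 -2.17 ± 0.07, adjusted p = 1.89e-13). The trehalose-phosphatase Os10g0553300, of an enzyme class that makes the sugar trehalose, was at 123 ± 6.05 CPM in HJX and 11.3 ± 2.64 CPM in HPS32 (log2 -3.44 ± 0.16, adjusted p = 1.84e-09). In all, 11507 genes differed, 5506 higher and 6001 lower in HPS32 (9862 and 3092 under total counts), and 2546 of them by at least 2-fold.

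The lowest in HPS32 relative to HJX was the short-chain dehydrogenase Os07g0691600 (22.5 ± 3.64 against 0.502 ± 0.462 CPM, log2 -5.46 ± 0.51). It was followed by the ribosome-inactivating protein Os03g0687400 (-4.75 ± 0.35), the seed storage-type cupin Os08g0189200 (391 ± 103 against 17.9 ± 5.25 CPM, -4.45 ± 0.34) and an unannotated BAH-domain transcript on chromosome 10, from 13756322 (-4.06 ± 0.28). The neighbouring chitinase-family genes Os11g0701100 and Os11g0701000 were at -4.06 ± 0.25 and -3.75 ± 0.40, the RNA-binding gene Os05g0223200 at -3.81 ± 0.14 (adjusted p = 5.68e-13), and the cytochrome P450 Os12g0582700 at -3.79 ± 0.28. Higher in HPS32 were the molybdenum cofactor oxidoreductase Os02g0770800 (2.1 ± 1.16 against 14.8 ± 1.85 CPM, 2.83 ± 0.26), the amino acid transporter Os04g0562100 (2.71 ± 0.46), the SINA-type ubiquitin ligase Os01g0123700 (2.60 ± 0.45) and the EB1-type microtubule gene Os10g0498900 (2.52 ± 0.61). The HMG-box gene Os02g0258200 and the multicopper oxidase Os01g0842400 were at 2.45 ± 0.61 and 2.43 ± 0.32. The cytochrome P450 genes Os08g0262500 and Os03g0371350 had no read in HJX and stood at 0.225 ± 0.0283 and 0.0869 ± 0.0307 CPM in HPS32, the latter with an adjusted p of 0.0379 that ranged from 0.0229 to 0.107 over its alternatives. The call of Os03g0371350 ended without any heat library but HPS32 heat library 3 (0.0712 to 0.0857).

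Of 235 ribosomal proteins 170 were higher in HPS32 and 8 lower (median 0.49, adjusted p = 3.2e-18, 0.117 with an estimated correlation), with L6, Os03g0356300, at 1.24 ± 0.10 and Os05g0169100 at -0.78 ± 0.08. Photosynthesis genes had 48 of 68 members higher and 2 lower (median 0.93, adjusted p = 1.78e-17, 0.117 with an estimated correlation), with Os01g0600900 at 1.56 ± 0.22 and Os09g0439500 at 1.54 ± 0.13. The chlorophyll gene Os03g0563300 was at 0.92 ± 0.10. Lipid transfer proteins had 21 of 46 members higher and 2 lower (median 0.56, adjusted p = 7.91e-05, 0.0434 with an estimated correlation), with Os12g0115500 at 1.72 ± 0.22. Cell wall genes had 48 of 120 members higher and 16 lower (median 0.41, adjusted p = 0.00158, 0.185 with an estimated correlation), with the pectinesterase Os04g0553500 at 2.08 ± 0.43. Phenylpropanoid genes had 16 of 38 members higher and 2 lower (median 0.71, adjusted p = 0.00165, 0.26 with an estimated correlation), with Os04g0116800 and Os11g0530600 at 2.33 ± 0.37 and 1.88 ± 0.36. Glutathione S-transferases had 18 of 57 members higher and 4 lower (median 0.29, adjusted p = 0.0229, 0.269 with an estimated correlation). Cytochrome P450 genes had 62 of 193 members higher and 23 lower (median 0.34, adjusted p = 0.0319, 0.334 with an estimated correlation). The aquaporins Os09g0541000 and Os10g0492600 were at 1.99 ± 0.24 and -3.33 ± 0.34, the wax gene Os09g0426800 at 1.25 ± 0.18 and the peroxidase Os05g0135500 at 1.90 ± 0.22.

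Sugar genes had 22 of 49 members lower in HPS32 and 5 higher (median -0.40, adjusted p = 5.12e-05, 0.0434 with an estimated correlation). The raffinose synthase Os08g0495800 was at -2.55 ± 0.22 and the trehalose synthesis gene Os08g0445700 at -1.91 ± 0.08. Autophagy genes had 19 of 25 members lower and 1 higher (median -0.42, adjusted p = 2.63e-05, 0.0992 with an estimated correlation), with Os03g0248000, of the Apg9 type, at -1.08 ± 0.06 and the ThiF-domain gene Os01g0614900 at -1.05 ± 0.07. Chaperones other than small heat shock proteins had 64 of 132 members lower and 19 higher (median -0.31, adjusted p = 0.000349, 0.117 with an estimated correlation), with the DnaJ gene Os06g0195800 at -1.81 ± 0.18. Ubiquitin genes had 265 of 697 members lower and 77 higher (median -0.21, turned to 0.05 under total counts, adjusted p = 0.00153, 0.0434 with an estimated correlation). Splicing factors had 11 of 15 members lower and 0 higher (median -0.40, adjusted p = 0.00493, 0.117 with an estimated correlation), with the SYF2 gene Os06g0711600 at -0.77 ± 0.07. NAC transcription factors had 22 of 69 members lower and 5 higher (median -0.04, turned to 0.21 under total counts, mean -0.28, adjusted p = 0.0132, 0.117 with an estimated correlation). Calcium sensors had 34 of 86 members lower and 8 higher (median -0.26, adjusted p = 0.0319, 0.391 with an estimated correlation, blocked adjusted p = 0.0799). Seed reserve and starch breakdown genes, markers of another tissue, had 5 of 14 members lower and 2 higher (median -0.27, adjusted p = 0.0433, 0.269 with an estimated correlation, blocked adjusted p = 0.0679), with the alpha-amylase Os08g0473900 at -2.75 ± 0.13. Heat stress transcription factors had 11 of 23 members lower and 1 higher without passing the list test (median -0.46, adjusted p = 0.0764), with Os06g0565200 at -1.66 ± 0.31. The small heat shock protein Os02g0711300 was at -1.44 ± 0.22 and the proteasome gene Os05g0557200 at -1.23 ± 0.09. Of the other marker lists, 0 of 16 organelle-encoded and 0 of 6 meristem genes differed, and 1 of 4 root markers was higher, the nicotianamine synthase Os07g0689600 (1.48 ± 0.46, adjusted p = 0.0176, 0.0551 to 0.0674 without HJX or HPS32 heat library 2 or 3). Adjusted over the list alone, the counts were the same except for ribosomal proteins (173 higher), photosynthesis (49 higher), chaperones (67 lower, 20 higher), ubiquitin (268 lower), cell wall (49 higher, 17 lower), NAC (21 lower, 4 higher) and heat stress transcription factor genes (13 lower, 3 higher).

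Of the G protein subunits RGA1 and GGC2 were higher in HPS32 under heat (0.33 ± 0.08, adjusted p = 0.00301, and 1.13 ± 0.44, adjusted p = 0.0469), and RGB1 and RGG2 lower (-0.27 ± 0.08, adjusted p = 0.00882, and -0.31 ± 0.09, adjusted p = 0.00668). RGG1 (0.55, adjusted p = 0.0507, blocked 0.0308) and DEP1 (-0.45, adjusted p = 0.177, blocked 0.0058) did not pass, with ranges over their alternatives of 0.00582 to 0.174 and 0.0058 to 0.53. The wax regulator WR2 was higher (0.30 ± 0.11, adjusted p = 0.0401) and WR1 did not pass (0.13, adjusted p = 0.69). The CAMTA genes Os10g0375600, Os03g0191000 and Os07g0490200 were lower (-0.85 ± 0.07, -0.42 ± 0.07 and -0.39 ± 0.07), Os01g0923600 was higher (0.31 ± 0.08), and Os04g0388500 did not pass (-0.15, adjusted p = 0.0875). Under total-count scaling the calls of RGB1 (0.916, range 0.00325 to 0.916), RGG2 (0.656, range 0.00472 to 0.656), Os03g0191000 (0.0684, range 1.44e-06 to 0.0684) and Os07g0490200 (0.125, range 3.83e-06 to 0.125) ended. With limma-voom those of WR2 (0.0561, range 0.000641 to 0.216) and GGC2 (0.0511, range 0.0103 to 0.162) ended. Single omissions ended those of RGB1 (HPS32 heat library 1, 0.0565), RGG2 (HJX heat library 1, 0.0594), WR2 (HJX heat library 1 or 2 or HPS32 heat library 2 or 3, 0.0598 to 0.216) and GGC2 (the same libraries, 0.12 to 0.162).

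**Figure D2:**
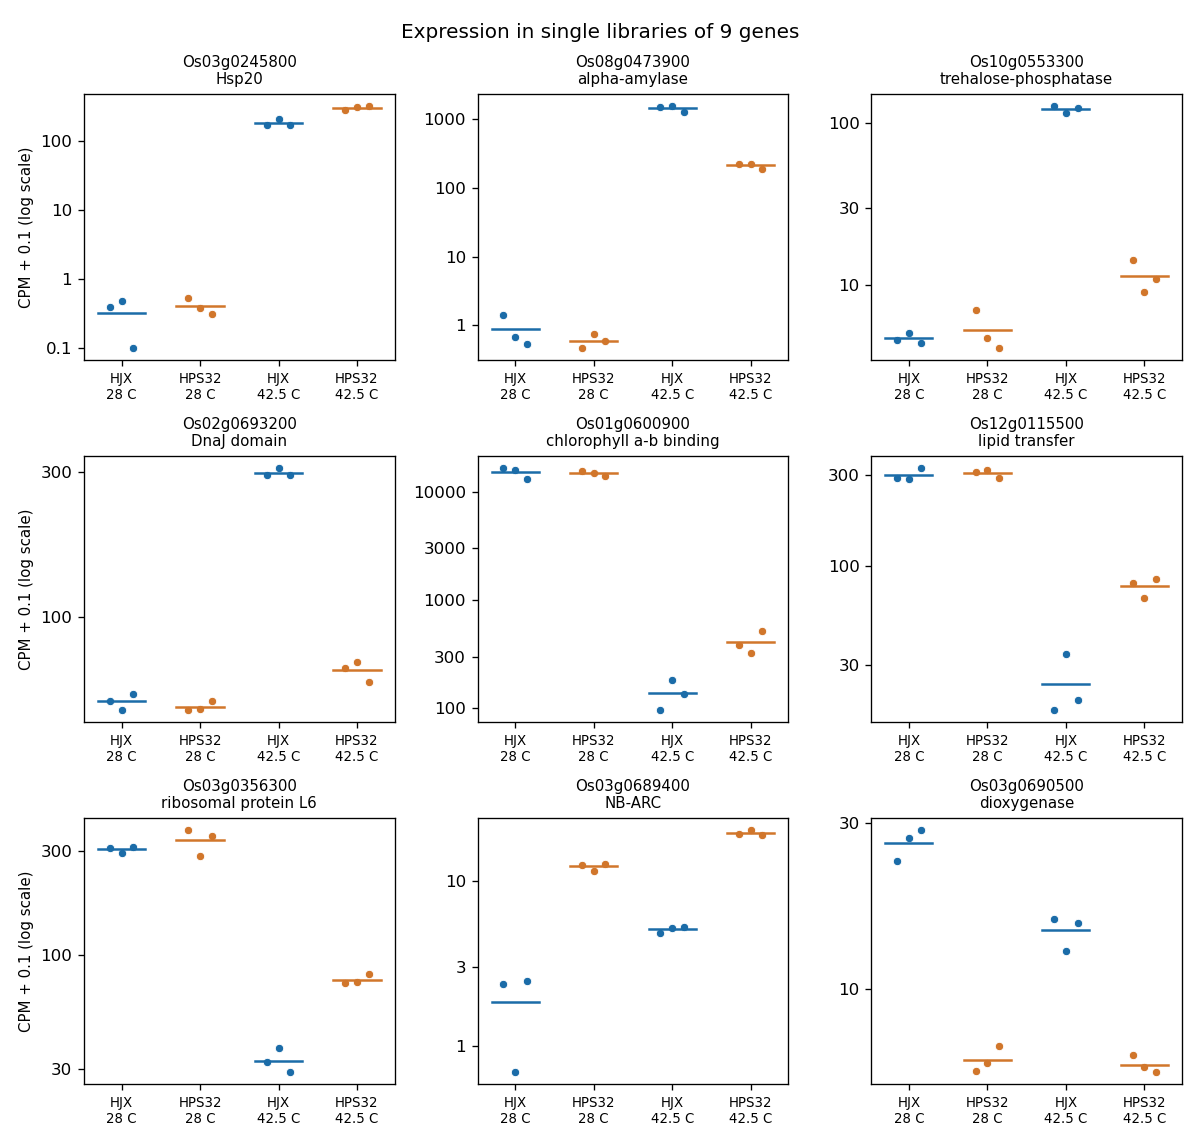
CPM plus 0.1 on a log axis for 9 genes, with points for single libraries and bars for the means of the 3 libraries of each group. The DnaJ gene Os02g0693200 averages 52.4 CPM in HJX and 50.2 CPM in HPS32 at 28 °C, and 299 and 66.3 CPM under heat.

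The fifth comparison tested whether the heat response itself differed between the lines, as the interaction of line and temperature. A positive value means that the log2 change under heat was higher in HPS32, as with a larger rise or a smaller fall. Calls were mostly negative among chaperones (22 in each direction under total counts), autophagy genes and genes of sugar transport, trehalose and raffinose, and mostly positive among photosynthesis and ribosomal protein genes. With an estimated correlation the sugar list passed (adjusted p = 0.04) and the other lists of that sentence did not (0.0769 to 0.163). The trehalose-phosphatase Os10g0553300 went from 4.56 ± 0.362 to 123 ± 6.05 CPM in HJX and from 5.13 ± 1.55 to 11.3 ± 2.64 CPM in HPS32 (interaction log2 -3.60 ± 0.27, adjusted p = 6.47e-07). The DnaJ gene Os02g0693200 went from 52.4 ± 3.12 to 299 ± 8.82 CPM in HJX and from 50.2 ± 1.88 to 66.3 ± 5.23 CPM in HPS32 (-2.11 ± 0.10, adjusted p = 1.34e-10). In all, 7473 genes passed, 3393 with a positive and 4080 with a negative value (6581 and 1900 under total counts), and 2108 of them with a difference of at least 2-fold. Of the 7473 genes, 4140 (55.4%) had a smaller response of the same sign in HPS32, 1452 (19.4%) a larger one, and 1881 (25.2%) fitted responses of opposite sign, both of them called in 521. This split was made with TMM scaling alone, and total counts moved the median interaction of all genes from 0.02 to 0.28.

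The lowest value was that of the clathrin gene Os11g0104866 (-7.13 ± 2.21, adjusted p = 0.0426, blocked 0.0501, range over its alternatives 0.00279 to 0.297). Next came the short-chain dehydrogenase Os07g0691600 (-6.14 ± 1.75), the chitinase-family genes Os11g0701000 (-5.40 ± 0.81) and Os11g0701100 (-4.89 ± 0.41) and the unannotated BAH-domain transcript (-4.74 ± 0.46). The cupin Os08g0189200 (-4.30 ± 0.46) rose from 21.6 ± 6.62 to 391 ± 103 CPM in HJX and stood at 19.5 ± 3.25 and 17.9 ± 5.25 CPM in HPS32. The neprosin-domain gene Os07g0179700 was at -3.84 ± 0.89 and the NAC gene Os11g0127600 at -3.67 ± 0.48. Among positive values, the hydrophobic seed protein gene Os06g0168700 (3.24 ± 0.47, adjusted p = 3.87e-05) went from 3.94 ± 1.23 to 0.618 ± 0.0748 CPM in HJX and from 1.31 ± 0.298 to 1.98 ± 0.45 CPM in HPS32. The Pumilio-type gene Os12g0493900 went from 0.189 ± 0.089 to 3.79 ± 0.904 CPM in HJX and from 0.0244 ± 0.0423 to 6.98 ± 1.28 CPM in HPS32. The kinase Os08g0512600, the EB1-type gene Os10g0498900 and the oxidoreductase Os02g0770800 were at 2.83 ± 0.65, 2.82 ± 0.70 and 2.78 ± 0.31. Calls ended in single omissions for Os11g0104866 (without any library but HPS32 replicate 1 and HJX heat library 2, 0.0677 to 0.103), Os07g0691600 (HJX replicate 2 or HPS32 replicate 1 or 2, 0.0506 to 0.257), Os12g0493900 (HJX replicate 1 or HPS32 replicate 2 or 3, 0.0507 to 0.0709) and Os07g0179700 (HPS32 replicate 3, 0.0794).

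Photosynthesis genes had 45 of 68 positive calls and 1 negative (median 0.87, adjusted p = 5.38e-17, 0.163 with an estimated correlation), with Os01g0600900 at 1.60 ± 0.30 and Os04g0457000 at 1.43 ± 0.23. Ribosomal proteins had 138 of 235 positive calls and 5 negative (median 0.47, adjusted p = 5.38e-17, 0.163 with an estimated correlation), with Os03g0356300 at 1.10 ± 0.14 and Os05g0169100 at -0.81 ± 0.11. Lipid transfer proteins had 17 of 46 positive calls and 2 negative (median 0.49, adjusted p = 4.53e-05, 0.04 with an estimated correlation), with Os12g0114800 at 1.26 ± 0.16. Cell wall genes had 35 of 120 positive calls and 10 negative (median 0.41, adjusted p = 0.00183, 0.199 with an estimated correlation), with the glycosyl hydrolase Os02g0151300 at 2.15 ± 0.34. Phenylpropanoid genes had 12 of 38 positive calls and 2 negative (median 0.57, adjusted p = 0.002, 0.282 with an estimated correlation), with Os04g0116800 at 2.16 ± 0.40. Wax genes had 5 of 16 positive calls and 0 negative (median 0.34, adjusted p = 0.0488, 0.514 with an estimated correlation, blocked adjusted p = 0.0773), with Os09g0426800 at 1.18 ± 0.25. The aquaporin Os09g0541000 was at 2.01 ± 0.29 and the Hsp20 gene Os07g0517100, which fell under heat in HJX, at 0.75 ± 0.10.

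Autophagy genes had 12 of 25 negative calls and 1 positive (median -0.56, adjusted p = 6.43e-06, 0.0769 with an estimated correlation), with Os01g0614900 and Os03g0248000 at -1.04 ± 0.10 and -1.04 ± 0.09. Sugar genes had 18 of 49 negative calls and 3 positive (median -0.43, adjusted p = 3.73e-05, 0.04 with an estimated correlation), with Os08g0495800 and Os08g0445700 at -2.80 ± 0.34 and -1.90 ± 0.12. Chaperones had 43 of 132 negative calls and 10 positive (median -0.29, adjusted p = 0.000314, 0.163 with an estimated correlation). The ClpB-type disaggregase Os02g0181900 went from 7.76 ± 0.197 to 65 ± 5.23 CPM in HJX and from 8.99 ± 1.46 to 22.9 ± 1.29 CPM in HPS32 (-1.71 ± 0.16, adjusted p = 2.11e-07). Ubiquitin genes had 193 of 697 negative calls and 56 positive (median -0.19, turned to 0.08 under total counts, adjusted p = 0.002, 0.04 with an estimated correlation). Splicing factors had 6 of 15 negative calls and 0 positive (median -0.34, adjusted p = 0.0219, 0.199 with an estimated correlation), with Os06g0711600 at -0.73 ± 0.10. NAC transcription factors had 15 of 69 negative calls and 4 positive (median -0.12, turned to 0.15 under total counts, adjusted p = 0.0469, 0.199 with an estimated correlation). Heat stress transcription factors had 7 of 23 negative calls and 0 positive without passing the list test (median -0.49, adjusted p = 0.106), with Os03g0224700 at -0.83 ± 0.11. Starch breakdown genes had 2 of 14 calls in each direction (median -0.46, adjusted p = 0.774), with the alpha-amylase Os08g0473900 at -2.14 ± 0.46. Root markers had 1 positive call of 4, meristem genes 1 of 6 (adjusted p = 0.358) and organelle-encoded genes 1 of 16 (adjusted p = 0.617). Adjusted over the list alone, the counts of the interaction were the same except for photosynthesis (46 positive), ribosomal (156 positive, 7 negative), cell wall (11 negative), phenylpropanoid (14 positive), autophagy (16 negative), sugar (19 negative), chaperone (46 negative, 11 positive), ubiquitin (203 negative, 63 positive), splicing (8 negative), heat stress transcription factor (8 negative) and meristem genes (0 positive).

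Of the always-reported genes 4 passed: the gamma subunit RGG2 (-0.33 ± 0.12, adjusted p = 0.0485) and the CAMTA genes Os10g0375600 (-0.75 ± 0.10, adjusted p = 1.84e-05), Os03g0191000 (-0.40 ± 0.10, adjusted p = 0.00473) and Os07g0490200 (-0.26 ± 0.10, adjusted p = 0.0488). The other G protein subunits, WR1, WR2 and CAMTA genes did not pass (adjusted p = 0.0839 to 0.617; WR2 0.37, adjusted p = 0.0935, blocked 0.0385, range 0.00633 to 0.253). Under total counts the calls of RGG2 (0.733, range 0.0315 to 0.733) and Os03g0191000 (0.345, range 0.00214 to 0.345) ended and Os07g0490200 turned to 0.00 (0.986, range 0.0112 to 0.986). The calls of RGG2 and Os07g0490200 also ended with RLE scaling (0.0889 and 0.102), no filter (0.0608 and 0.0676), DESeq2 (0.107 and 0.0845) and the length offset (0.109 and 0.0937). Total counts brought RGA1 (0.00182, range 0.00182 to 0.254), Os01g0923600 (0.002, range 0.002 to 0.214) and WR2 (0.00633) past the threshold, and Os01g0923600 passed with RLE (0.0443) and the length offset (0.038) too. Single omissions ended the call of RGG2 except for HJX and HPS32 heat library 2 (0.0523 to 0.16) and that of Os07g0490200 except for HPS32 replicate 1 (0.0579 to 0.126).

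The authors' deposited DESeq2 tables were compared for the 4 pairs of groups they cover. Under the same threshold they list 18142 genes for heat in HJX and 17061 for heat in HPS32. They list 40 for the lines at 28 °C and 11299 under heat. Of these, 17506, 16506, 19 and 10572 were also called here, all with the same sign.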

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

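The tests of scaling and of windows other than that from 15 to 18 Mb of chromosome 3, the upper limits of r, the length offset, and what would decide the planned count of called genes within 5 Mb of TT2 were chosen only after the result was seen. Each result below stands out because the heat response differed between the lines in the interaction test. Positive values again mean a higher log2 change in HPS32. In all, 7473 genes passed. Of the lists written before, medians were negative for chaperones other than small heat shock proteins (-0.29), autophagy (-0.56), sugar (-0.43), splicing (-0.34), ubiquitin (-0.19, turned to 0.08 under total counts) and NAC genes (-0.12, turned to 0.15 under total counts). They were positive for photosynthesis (0.87), phenylpropanoid (0.57), lipid transfer (0.49), ribosomal (0.47), cell wall (0.41) and wax genes (0.34). Cytochrome P450 genes (median 0.37) had 43 of 193 positive calls and 17 negative (adjusted p = 0.00864, 0.282 with an estimated correlation). Glutathione S-transferases (0.18) had 15 of 57 positive and 3 negative (adjusted p = 0.0279, 0.315 with an estimated correlation). Cyclins, kinesins and other mitosis genes (0.21) had 32 positive and 11 negative calls, and histone and DNA replication genes (0.12) 22 and 13, each with an adjusted p of 0.0469 (adjusted p = 0.356 and 0.598 with an estimated correlation). With an estimated correlation 3 of these lists passed: lipid transfer, sugar and ubiquitin genes. Of the added lists, class III peroxidases (median 0.52) and PPR proteins (0.27) passed with both correlations (adjusted p = 0.041 and 0.0493 with the estimated one). Those that did not pass with the estimated correlation were terpene synthases (0.94, adjusted p = 0.0118 and 0.209), UDP-glycosyltransferases (0.37, 36 positive calls and 8 negative, 37 and 8 alone, adjusted p = 0.00414 and 0.209) and NB-ARC genes (0.32, 30 and 6, 22 and 4 alone, adjusted p = 0.00827 and 0.257).

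The most negative single-gene interactions were those of Os11g0104866 (-7.13), Os07g0691600 (-6.14), Os11g0701000 (-5.40), Os11g0701100 (-4.89) and the unannotated BAH-domain transcript (-4.74). The most positive among genes with enough reads in every group was that of Os06g0168700 (3.24). Fitted values of Os08g0262500 (4.66), Os03g0371350 (4.04), Os12g0493900 (3.50) and the F-box gene Os03g0366350 (2.99) rest on groups with 0 to 3 reads and are no bounds. The call of Os03g0371350 ended without any heat library but HPS32 heat library 3 (adjusted p = 0.0629 to 0.0793). Sugar genes with negative values were Os10g0553300 (-3.60), Os08g0495800 (-2.80) and Os08g0445700 (-1.90). Chaperone and heat stress genes with negative values were Os02g0693200 (-2.11), Os02g0181900 (-1.71) and the heat stress transcription factor Os03g0224700 (-0.83), while the Hsp20 gene Os07g0517100 was at 0.75. The alpha-amylase Os08g0473900 was at -2.14, the peroxidase Os06g0695500 at -2.15, the autophagy genes Os01g0614900 and Os03g0248000 at -1.04 each, the splicing gene Os06g0711600 at -0.73 and the ribosomal protein Os05g0169100 at -0.81. RGG2 was at -0.33 and the CAMTA genes Os10g0375600, Os03g0191000 and Os07g0490200 at -0.75, -0.40 and -0.26. Most omissions ended the calls of RGG2, Os07g0490200 and Os11g0104866. Values were positive for the chalcone or stilbene synthase Os04g0116800 (2.16), the glycosyl hydrolase Os02g0151300 (2.15), the aquaporin Os09g0541000 (2.01) and the terpene synthase Os04g0178300 (2.01). The same held for the chlorophyll-binding genes Os01g0600900 (1.60) and Os04g0457000 (1.43), the lipid transfer gene Os12g0114800 (1.26), the wax gene Os09g0426800 (1.18) and ribosomal protein L6, Os03g0356300 (1.10). Of these, Os01g0600900 and Os09g0541000 fell under heat in both lines, and by less in HPS32.

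The first pattern is the smaller heat response in HPS32 of 4140 of the 7473 genes with TMM, against 1452 with a larger one. Genes that rose at least 2-fold in both lines showed it little (median interaction -0.06). Unheated RNA mixed into the HPS32 heat libraries would give 1 share for all genes, but the implied median share was 47.4% for the 455 genes that rose at least 8-fold in HJX and 5.26% for the 873 that fell, a gap of 42.1 percentage points (SD 0.866 over libraries), which argues against it as the whole cause. A scaling error moves all genes alike, while the median interaction of genes that fell at least 2-fold in both lines (0.38, 4065 genes) lay 0.44 above that of genes that rose as much (-0.06, 3437 genes; SD 0.0218 over omissions), and 95.2% of the calls remained with the length trend as offset, which argues against either as the whole cause. Unheated RNA stays open for the falling genes on their own, of which 1.49% were lower still in HPS32 under heat and 56.5% were higher. The loss of TT2 function, which the labels name, donor DNA and heat groups of 1 sample each stay open, all untested for this pattern.

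The second pattern is the set of genes that differed between the lines at 28 °C. Donor DNA around TT2 as their source cannot be told apart from chance placement, since 1 gene, 4.545% of the calls, lay within 5 Mb (Fisher's exact test, p = 0.404), while with the replicate block the share was 7.58% (Fisher's exact test, p = 0.0186). Line differences at 28 °C and under heat, which share no library, would correlate across a window where donor DNA altered most genes at both temperatures. In the 3 Mb window from 15 to 18 Mb, which holds TT2, r was 0.0966 (95% upper limit 0.252 across genes). In the windows from 14 to 17 Mb and from 16 to 19 Mb, which hold it too, r was 0.0248 and 0.198. The upper limit lay below the 95th percentile of 0.359 over 357 windows, which argues against a difference shared by most genes there. The lines carry different TT2 alleles, so a low r does not exclude donor DNA from a window. The window from 27 to 30 Mb holds 4 genes called at 28 °C. Its r was 0.267, and 0.149 without them. The upper limit of the first, 0.381, lay above that percentile, so shared donor DNA cannot be told apart from chance there. Donor DNA elsewhere stays open, with r of 0.78 on chromosome 12 from 5 to 8 Mb (0.0266 without the genes called at 28 °C) and 0.512 to 0.546 in the windows of chromosome 1 between 29 and 34 Mb, and so does the loss of TT2 function, which was not tested.

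The 3 against 3 comparisons have 10 splits each, too few for a share under 0.05. For heat in HJX 1 split gave as many genes (real 19079, highest other 0), for heat in HPS32 1 (17925, highest other 0), for the lines under heat 1 (11507, highest other 0) and for the lines at 28 °C 2 (22, highest other 482). The split with 482 genes put the number 1 libraries of both lines against the number 3 libraries and parted number 2, and the only other split that does so gave 10. It points to a structure of the 28 °C libraries that the replicate numbers follow only in part, since the 4 further splits that keep some numbers together gave 0 to 2. The 3 other splits that part all 3 numbers as the real one does gave 0 genes, and with the replicate block the lines differed in 66. For the interaction 5 of 100 splits gave as many genes (real 7473, highest other 8348), so this share does not exclude chance. The share is no null for the difference under heat, since the splits as large as the real one all kept the heat groups whole and exchanged only 28 °C libraries, where the lines differed in 22 genes. The 8 other splits of that kind gave 7187 to 8348 genes, and the 91 that mixed the heat groups gave 0 to 1.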

How the results depend on the processing

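Alternatives chosen only after the data were seen were the length offset, the block confined to 28 °C libraries, the fit of that block on the 6 libraries at 28 °C, and the lists as first written. Single-gene results kept their side of the threshold in 3863 of 4042 values over 246 results, lost it in 144, gained it in 27 and changed sign, with a call before or after, in 8. Signs that turned where neither value was called are not counted. Of 210 called gene results 187 kept the call in every omission of a library, 23 lost it in some and 0 changed sign. A threshold of 2-fold, which by construction calls fewer genes, left 10796 genes for heat in HJX, 9246 for heat in HPS32, 12 for the lines at 28 °C, 2546 for the lines under heat and 2108 for the interaction. For the lines at 28 °C the count of 22 was 49 with DESeq2, 13 with limma-voom, 12 in the fit on the compared groups, 66 with the replicate block and 79 with the block on the 6 libraries at 28 °C; the cause was not tested. The block gave 19638, 18551, 12666 and 8581 genes in the other comparisons, 19055, 17890, 11485 and 7446 of them called without it. Of the 246 results it changed only calls printed beside them.

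Lists past the threshold fell from 17 to 2 (heat in HJX), 12 to 0 (heat in HPS32), 15 to 3 (lines under heat) and 16 to 3 (interaction) with the estimated correlation, and rose to 35, 35, 28 and 25 with fry, which by construction compares no list with other genes. At 28 °C the block gave 3 lists against 0. The slope of the heat responses was 0.873 over genes called in both lines, and r was 0.906 with the stricter filter. The r of the line differences at 28 °C and under heat was 0.121 over genes called in either, 0.0591 over all genes and 0.962 over the 15 called in both. The share of calls near TT2 was 31.8% at 28 °C and 13.9% under heat on the whole chromosome, wider by construction, and 7.58% at 28 °C with the block. Under total counts the sign turned, with a call before or after, for heat in HPS32 at Os03g0669200 (0.539), Os05g0333200 (0.186), Os06g0604000 (0.41), Os10g0375600 (0.523), Os03g0191000 (0.503), Os07g0490200 (0.425) and Os04g0388500 (0.061), and for the interaction at Os07g0490200 (0.003), where the median of all genes under total counts is 0.54 and 0.28. All causes not given were not tested.

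Omission of each library gave 18147 to 18669 genes for heat in HJX and 16931 to 17272 for heat in HPS32. It gave 8 to 26 for the lines at 28 °C, 9682 to 10694 under heat and 6161 to 7322 for the interaction. Lists past the threshold were 15 to 16, 10 to 12, 0 to 7, 13 to 16 and 12 to 16 in the same order. The slope lay between 0.839 and 0.878, r of the heat responses between 0.877 and 0.895, and r of the line differences between 0.0535 and 0.157. The 28 °C share near TT2 lay between 0% and 5.56%, and that under heat between 2.38% and 2.51%. Depth limits genes without reads in a group to a bound. With such genes at their bounds 214 of 230 medians of lists with at least 5 tested genes did not move, and the largest shift among these was 0.56, for organelle-encoded genes in HPS32. The median of the 4 root markers moved by 1.02 for heat in HJX, 0.99 for the interaction and 0.55 for the lines under heat.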

Other observations

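The lists below are the added ones, adjusted among themselves. PPR proteins, which process RNA inside plastids and mitochondria, mostly rose under heat. In HJX 296 of 403 rose and 39 fell (297 and 39 adjusted over the list alone, mean log2 1.09, adjusted p = 5.92e-07, 0.00201 with an estimated correlation). In HPS32 326 rose and 27 fell (330 and 27 alone, mean 1.40, adjusted p = 2.67e-15, 0.000585 with an estimated correlation), and the gene Os06g0700100 went from 0.0479 ± 0.0415 to 2.05 ± 0.175 CPM in HPS32. Under heat 119 PPR genes were higher in HPS32 and 13 lower (110 and 13 alone, median 0.30, adjusted p = 0.000544, 0.0466 with an estimated correlation). The interaction had 57 positive and 8 negative calls (40 and 7 alone, adjusted p = 0.00394, 0.0493 with an estimated correlation).

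Class III peroxidases, which cross-link cell walls, mostly fell. In HJX 62 of 90 fell and 10 rose (the same alone, median -1.70, adjusted p = 5.92e-07, 0.00186 with an estimated correlation), with Os02g0240300 at -6.58 ± 0.24 and Os05g0162000 at 3.83 ± 0.15. In HPS32 60 fell and 9 rose (61 and 9 alone, median -1.20, adjusted p = 7.81e-06, 0.00168 with an estimated correlation), with Os02g0240300 at -6.81 ± 0.25. Under heat 34 were higher in HPS32 and 11 lower (38 and 13 alone, median 0.43, adjusted p = 0.0162, 0.0532 with an estimated correlation), and the interaction had 25 positive and 5 negative calls (26 and 5 alone, adjusted p = 0.00394, 0.041 with an estimated correlation). The peroxidase Os06g0695500 rose from 18.7 to 37.4 CPM in HJX and fell from 16.3 to 7.33 CPM in HPS32. Terpene synthases fell in HJX (12 of 21 down, 3 up, median -2.28, adjusted p = 0.0221, 0.269 with an estimated correlation) and had 7 positive and 0 negative interaction calls (adjusted p = 0.0118, 0.209 with an estimated correlation). Of 6 KNOX genes 5 fell in HJX (median -1.43, adjusted p = 0.00574, 0.039 with an estimated correlation). In HPS32 4 fell (median -0.55, turned to 0.02 under total counts, adjusted p = 0.0143, 0.0725 with an estimated correlation).

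Of 21 ketoacyl-CoA synthases, which lengthen wax precursors, 14 fell in HJX and 0 rose (median -0.87, adjusted p = 0.00605, 0.269 with an estimated correlation), and 15 fell in HPS32 and 1 rose (median -0.75, adjusted p = 0.0143, 0.362 with an estimated correlation). In HJX Os03g0382100 of this family fell by 3.71 ± 0.31. UDP-glycosyltransferases, which attach sugars to small molecules, had 66 of 122 members down and 35 up in HJX (median -0.75, adjusted p = 0.032, 0.269 with an estimated correlation, blocked adjusted p = 0.0521). Under heat 43 were higher in HPS32 and 11 lower (42 and 11 alone, median 0.31, adjusted p = 0.0141, 0.252 with an estimated correlation), and Os03g0841600 rose by 4.27 ± 0.32 in HJX and 4.51 ± 0.32 in HPS32. NB-ARC genes of the immune receptor type had 111 of 256 members up and 55 down in HPS32 (median 0.40, adjusted p = 0.0143, 0.362 with an estimated correlation), and 62 were higher in HPS32 and 23 lower under heat (median 0.24, adjusted p = 0.0162, 0.361 with an estimated correlation). Of 67 bZIP transcription factors 24 were lower and 10 higher in HPS32 under heat (median -0.23, turned to 0.03 under total counts, adjusted p = 0.018, 0.169 with an estimated correlation). In the interaction 17 had negative and 7 positive calls (18 and 7 alone, median -0.25, turned to 0.02 under total counts, adjusted p = 0.0547, 0.209 with an estimated correlation, blocked adjusted p = 0.0427).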
